A study of Mus musculus with 2 samples.

How the data were processed

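Gene expression was measured on 2 single-channel microarrays hybridised with biotin-labelled mouse RNA, 1 array from Id1 knockout embryonic stem (ES) cells and 1 from wild-type ES cells. Per the labels' protocols, total RNA was purified with RNeasy columns and 1 ug was labelled with an in vitro transcription kit. The deposited values are linear intensities, 1 per probe set, and scanner files, detection calls and the software that made the values are not given in the sources used here. The probe set names and the control probe sets are those of an Affymetrix mouse array. The deposited intensities ran from 0.0977 to 39378 on the knockout array and from 0.342 to 39542 on the wild-type array. With 2% of the probe sets trimmed from each end, both arrays had a mean intensity of 500.2, so the 2 arrays had been brought to a common scale before deposit, although no source states how. A single scaling factor per array leaves any intensity-dependent difference between the arrays in place, and values of dim probe sets on such a scale are noisy.

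The table held 22690 probe sets, of which 64 were controls. Of the other 22626, the platform annotation of 2016 assigned 20380 to 1 gene symbol and 691 to several, and 1555 had no symbol in it. Gene identifiers of 20364 probe sets matched the RefSeq gene table of the mouse assembly GRCm38.p6, and no symbol had to be changed. That table was used for synonyms of gene symbols, for the chromosome of each gene and for the order of genes along it. No probe set was assigned to Brachyury in the annotation used here, so that gene was not analysed.

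All settings that follow were chosen before the data were examined unless stated otherwise. Intensities were converted to log2 and each array's median over the non-control probe sets was subtracted, which removed a shift of 0.02 on the log2 scale. A floor was then set at the 25th percentile of the centred values, equal to an intensity of 48.4 on the knockout array and 47.6 on the wild-type array, and a difference with 1 side at the floor is a lower bound. A gene was represented by its probe set with the highest mean log2 value, and it entered the comparison when the brighter of its values lay at or above its array's median (155.0 on the knockout array and 152.5 on the wild-type array). Of 12393 genes with a probe set, 7369 passed. Differences are knockout minus wild type throughout, and a gene was counted as higher or lower when the difference was at least 2-fold.

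With 1 array per genotype there were no replicates, so no test between genotypes and no p-value was computed, and the difference between the arrays has no replicate check. Cultures, clones and array batches cannot be told apart from genotype. The errors that could be had were technical. Over 2566 genes with at least 2 probe sets past the filter, the SD of the log2 difference between probe sets of the same gene had a median of 0.22. The 18 hybridization spike probe sets had an SD of 0.22 in their log2 difference. The number of arrays limits the precision.

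Genes were named by a fixed rule: Id1, Nanog, Pou5f1, Sox2 and Zeb1 whatever their value, the 12 largest differences in each direction among genes above the floor on both arrays and with all passing probe sets going the same way, the 4 largest bounds in each direction, and the members past 2-fold of each gene list, up to the 4 largest. Members named beyond these were chosen after their values were seen. No gene was skipped for having only a clone name. For each of 34 gene lists and for each chromosome, the median log2 difference of the genes past the filter was set against the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean brightness. The 95% range of those medians describes these 2 arrays and is not a test of genotype, since genes are not replicates. Lists share some genes. With 32 lists large enough to compare, 1.6 would fall outside a 95% range by chance if lists and the genes within each list were independent. Random lists hold unrelated genes, whereas members of a list can move together between any 2 cultures. More than 1.6 can therefore fall outside without any effect of genotype.

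The procedure was checked on simulated arrays built from the wild-type values with normal noise added. The size of that noise at each brightness was a robust SD (from the median absolute deviation) of the log2 difference between the 2 real arrays. In that simulation of the knockout and wild-type comparison over 7473 genes, 8% of genes changed 1.5-fold were counted, against 58% of those changed 2-fold, 94% of those changed 3-fold and 100% of those changed 4-fold. Of the unchanged genes 4.69% were counted. That robust SD contains real differences between the arrays but gives little weight to the largest differences. It may therefore overstate or understate technical noise. Of 40 simulated lists of 15 genes with no shift, 3 lay outside the 95% range, and 34 of 40 lists shifted by 0.5 lay above it. Alternatives covered the scaling (none, quantile, loess), the floor, the brightness filter, the choice of probe set, the fold threshold and the matching of random lists, and detection calls could not be tried because the table holds none. A count without genes of the sex chromosomes was added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.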

Results

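The transcriptomes of Id1 knockout and wild-type mouse ES cells were compared on microarrays, with 1 array for each genotype. Both cultures were kept on gelatin in medium with serum and leukaemia inhibitory factor (LIF), the cytokine that holds mouse ES cells in self-renewal. Id1 encodes a helix-loop-helix protein without a DNA-binding domain that is induced by BMP signalling and sequesters E proteins. The comparison asked which transcripts differ between Id1 knockout and wild-type ES cells held under self-renewing conditions, and the study's title names Nanog and Brachyury. Brachyury was not analysed here because no probe set carried its name.

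The Id1 probe set had an intensity of 461 on the knockout array and 1045 on the wild-type array, which is 2.30-fold lower in the knockout (log2 difference -1.20). The knockout signal was still above the array median of 155.0. The labels do not say which part of the gene was removed, so signal from the remaining part cannot be excluded and this probe set checks the labels only in part.

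Of 7369 genes past the brightness filter, 289 were at least 2-fold higher and 289 at least 2-fold lower in the knockout, together 7.84% of the genes. At least 4-fold differences were seen for 46 genes in the upward and 39 in the downward direction. On simulated arrays with normal noise of the robust SD between the 2 real arrays, 4.69% of unchanged genes lay past 2-fold. The robust SD gives little weight to the largest differences, so this share does not show how many of the 7.84% are noise. Among genes with several passing probe sets, all probe sets went the same way in 72 of 73 genes that were higher and in 60 of 66 that were lower. Over all 2566 genes with several passing probe sets, the probe sets went 1 way in 56.8%, and in 64.0% of the 1719 genes with exactly 2, against 50% by chance. The median SD between probe sets of the same gene was 0.22 on the log2 scale. Values given for a gene are those of its brightest probe set, and another passing probe set stayed under 2-fold for some genes named below as past it, namely Dnmt3a, Nes, Zic5, Sox4, Fgf4, Dusp9, Inhbb, Jun, Lamb1, Mmp2, Xbp1, H2-D1 and H2-K1. Intensities of the 2 arrays correlated with a Pearson r of 0.934 across probe sets, which are not independent replicates. Among the control probe sets, the 3' to 5' ratio for actin was 1.10 in the knockout and 1.07 in the wild type, for Gapdh 0.761 and 0.749, for pyruvate carboxylase 1.32 and 1.45, for the transferrin receptor 2.30 and 1.85, and for 18S ribosomal RNA 0.541 and 0.166. The last difference came mostly from the 5' probe set, which read 791 in the knockout and 2209 in the wild type.

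**Figure D1:**
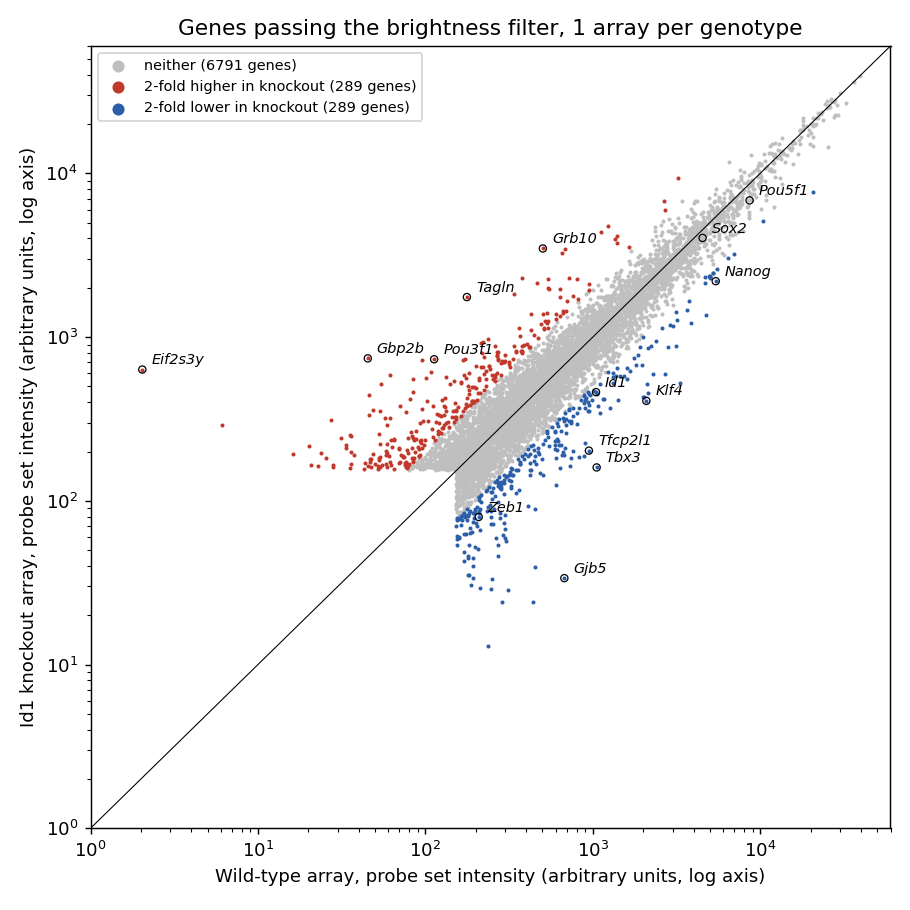
Probe set intensity on the knockout array (vertical, log axis, arbitrary units) against the wild-type array (horizontal, log axis, arbitrary units) for the 7369 genes past the brightness filter, 1 point per gene. The 289 genes 2-fold higher and 289 genes 2-fold lower in the knockout are coloured, the line marks equal intensity, and Nanog and Klf4 lie below it while Pou5f1 and Sox2 lie near it.

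The largest increases with both values above the floor included genes of the contractile cytoskeleton. Tagln, an actin-binding protein of smooth muscle, was 9.76-fold higher in the knockout, the myosin light chain gene Myl9 9.33-fold and the tropomyosin gene Tpm1 5.99-fold. The interferon-inducible GTPase gene Gbp2 was 9.38-fold higher, the keratin gene Krt19 7.39-fold, the semaphorin gene Sema3e 7.27-fold and the imprinted adaptor gene Grb10 6.80-fold. Igfbp3, an IGF-binding protein, was 6.50-fold higher, and the transcription factor genes Sox11 and Pou3f1 were 6.49-fold and 6.38-fold higher. Car4, a carbonic anhydrase, was 5.56-fold higher and Prickle1, a planar cell polarity gene, 5.51-fold. The wild-type signal lay close to the floor of 47.6 for Sema3e (48.4), Sox11 (53.6), Myl9 (54.4), Prickle1 (57.4) and Gbp2 (61.7). The size of their folds is therefore uncertain. Signals at the floor on the wild-type array gave bounds of at least 15.3-fold for Gbp2b, at least 13.1-fold for the Y-linked gene Eif2s3y, at least 9.14-fold for Anxa5 and at least 6.87-fold for Clasrp. Gbp2 and Gbp2b are close paralogs, and their probe sets can share signal.

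The largest decreases included several transcription factors of the naive pluripotent state. Tbx3 was 6.70-fold lower in the knockout, Klf4 5.21-fold and Tfcp2l1 4.76-fold. Jam2, an adhesion molecule gene of naive ES cells, was 4.83-fold lower with all 4 of its probe sets lower. The lysosomal mannosidase gene Manba was 6.36-fold lower, the integrin gene Itgb7 5.41-fold and Arhgef10l 5.17-fold. Jdp2, which encodes a bZIP repressor, was 5.13-fold lower, the imprinted zinc finger gene Plagl1 5.10-fold, the small GTPase gene Mras 4.88-fold, the hypoxia-inducible factor gene Epas1 4.81-fold and the myosin light chain gene Mylpf 4.77-fold. Close to the floor of 48.4 lay the knockout signal of Arhgef10l (53.7), Itgb7 (56.9), Jdp2 (59.1) and Epas1 (61.5), so the size of these folds is uncertain. Signals at the floor on the knockout array gave bounds of at least 14.2-fold for the connexin gene Gjb5, at least 9.50-fold for Pramel6, at least 9.23-fold for the myosin gene Myo1f and at least 6.50-fold for Myof.

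Pluripotency genes differed to very different degrees. Nanog, a homeobox factor that sustains self-renewal, was 2.51-fold lower, with intensities of 2195 and 5423. Pou5f1 was 1.28-fold lower (6834 against 8636) and Sox2 1.14-fold lower (4032 against 4526), both short of 2-fold. Of 14 core pluripotency genes past the filter, 2 were 2-fold lower (Nanog and the growth factor gene Fgf4, 2.55-fold), none was 2-fold higher and 12 were neither. Of the 14, 5 had log2 differences above 0, namely Utf1 (0.44), Lin28a (0.43), Sall4 (0.30), Dppa4 (0.10) and Rif1 (0.06). For Lin28a, only 1 of 2 passing probe sets was higher. The median log2 difference of -0.37 lay below the 95% range of random lists, -0.23 to 0.15. Of 17 naive pluripotency genes, 7 were 2-fold lower and 10 were neither, and Gbx2 (0.19) and Dppa3 (0.10) were above 0. The median of the naive list was -0.86, below all 10000 random lists. Besides Tbx3, Klf4, Tfcp2l1 and Jam2, the members past 2-fold were the nuclear receptor genes Nr0b1 (4.61-fold) and Esrrb (2.74-fold) and the AKT coactivator gene Tcl1 (3.92-fold).

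Genes of the primed, post-implantation epiblast went the other way. Of 15 such genes past the filter, 9 were 2-fold higher in the knockout, none was 2-fold lower and 6 were neither. The list median of 1.23 lay above all 10000 random lists. Its largest members were Sox11, Pou3f1, the SRY-box gene Sox4 (5.29-fold, all 5 probe sets higher) and the kinase gene Pim2 (5.01-fold). The de novo DNA methyltransferase gene Dnmt3a was 3.54-fold higher, although 1 of its 4 passing probe sets had a log2 difference of 0.10. Dnmt3b was 1.63-fold higher by its brightest probe set (6751 against 4073), and its other passing probe set read 5380 against 1519 (log2 difference 1.80). Fgf5, a marker of the epiblast, stayed below the filter on both arrays, at 82.1 in the knockout and 15.7 in the wild type, and Nodal and Foxd3 had log2 differences of -0.73 and -0.52. Of 11 neuroectoderm genes, 3 of them shared with the primed list, 5 were 2-fold higher and none was 2-fold lower (median 0.90, above all random lists). The largest were Sox11, Zic5 (2.96-fold), the retinoic acid-binding protein gene Crabp2 (2.63-fold) and the neural progenitor filament gene Nes (2.14-fold, with 0.15 on the log2 scale for its other passing probe set), while the neural factor genes Pax6 and Sox1 did not reach the filter.

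**Figure D2:**
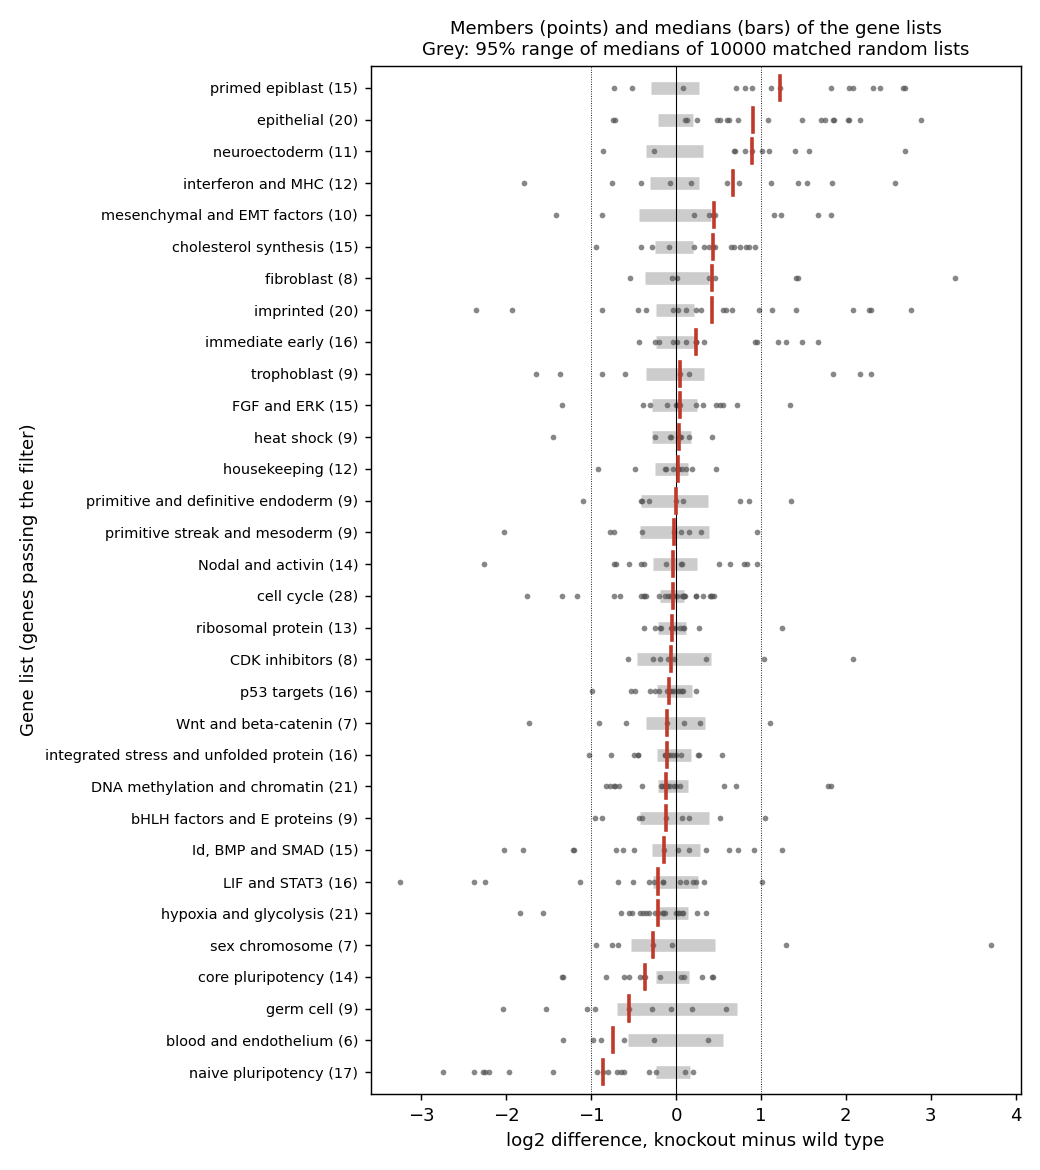
Log2 difference, knockout minus wild type (horizontal), of the genes past the filter in each list (points, number in brackets) with the list median (bar) and the 95% range of medians of 10000 brightness-matched random lists (grey). The naive pluripotency list has the lowest median at -0.86 and the primed epiblast list the highest at 1.23.

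Lists of mesoderm, endoderm and trophoblast markers had medians inside the random range, and most of their genes did not reach the filter. Of 31 primitive streak and mesoderm genes on the array, 22 did not reach the filter. Among the 9 that did, the growth factor gene Bmp4 was 4.07-fold lower, none was 2-fold higher, and the list median of -0.03 lay inside the random range. Of 9 endoderm genes, the laminin gene Lamb1 was 2-fold higher (2.55-fold) and the apolipoprotein gene Apoe 2-fold lower (2.14-fold), with a median of -0.01. Gata4, Gata6 and Sox17 did not reach the filter on either array. Of 9 trophoblast genes, 3 were 2-fold higher, namely Phlda2 (4.91-fold), Krt8 (4.50-fold) and Krt18 (3.60-fold), and 2 were lower, namely the homeobox genes Rhox6 (3.15-fold) and Rhox9 (2.59-fold), with a median of 0.05. In the blood and endothelium list, Kit was 2.53-fold lower and the median of the 6 genes was -0.75, below the random range, although it lay inside that range under 3 alternative settings. In the germ cell list, Stk31 (4.11-fold), Dazl (2.90-fold) and Taf7l (2.07-fold) of 9 genes were lower, with a median of -0.56 inside the range. Of the two-cell-stage genes 1 and of the Hox genes 2 passed the filter, too few for a median.

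Epithelial genes were higher in the knockout. Of 20 such genes past the filter, 10 were 2-fold higher, none was 2-fold lower and 10 were neither, and the median of 0.91 lay above all random lists. Besides the keratins Krt19, Krt8 and Krt18, these included the tight junction genes Cldn6 (4.10-fold), Cldn7 (4.07-fold) and Ocln (3.63-fold), the splicing regulator gene Esrp1 (3.27-fold) and the E-cadherin gene Cdh1 (2.12-fold). Zeb1, a repressor of Cdh1, was 2.66-fold lower, at 79.6 against 208. In the list of mesenchymal genes and transition factors, 4 of 10 were 2-fold higher, namely the matrix metalloproteinase genes Mmp2 (3.54-fold) and Mmp14 (2.36-fold), the connective tissue growth factor gene Ccn2 (3.20-fold) and the integrin gene Itga5 (2.22-fold). Zeb1 was the member that was 2-fold lower, and the median was 0.44. Of 8 fibroblast genes, Tagln, Fstl1 (2.71-fold) and the thrombospondin gene Thbs1 (2.67-fold) were 2-fold higher, with a median of 0.43, while the collagen genes Col1a1 and Col3a1 did not reach the filter on either array. Both medians lay above the random range in the chosen setting, the mesenchymal one inside it under 1 alternative and the fibroblast one inside it under 2.

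Among signalling genes, the BMP and SMAD list had 4 of 15 members 2-fold lower, namely Bmp4, the ERK phosphatase gene Dusp9 (3.50-fold), the inhibitory Smad6 (2.32-fold) and Id1. Its member Id2 was 2.37-fold higher and Id3 had a log2 difference of 0.16, with a list median of -0.15 inside the random range. Of 16 LIF and STAT3 genes, 4 were 2-fold lower, namely Pramel6, Klf4, Tfcp2l1 and Bcl3 (2.19-fold), and Jak2 was 2.02-fold higher. The median of that list was -0.21, inside the range, and the direct STAT3 target Socs3 had a log2 difference of 0.05 by its brightest probe set and -0.39 and -0.33 by the other two. In the FGF and ERK list of 15 genes, the feedback phosphatase gene Dusp6 was 2.55-fold higher and Fgf4 was lower (median 0.05). In the Wnt list of 7, Fzd7 was 2.16-fold higher and Notum 3.31-fold lower (median -0.10), and in the Nodal and activin list of 14, Inhbb was 4.80-fold lower with its 2 probe sets going opposite ways (median -0.03). Of 9 bHLH genes, Bhlhe40 was 2.07-fold higher (median -0.12), and the E-protein genes Tcf3, Tcf4 and Tcf12 had log2 differences of -0.12, 0.08 and 0.52. The other passing probe set of Tcf3 gave 0.24. The 3 passing probe sets of Tcf4 disagreed, with 0.08 for the brightest on average and -1.06 and -0.70 for the others.

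Of 28 cell cycle genes, 25 differed by less than 2-fold, and the median of -0.04 lay inside the random range. The exceptions were the D-type cyclin genes Ccnd2 (3.38-fold lower, all 5 probe sets) and Ccnd3 (2.54-fold lower) and the transcription factor gene E2f1 (2.25-fold lower). Of 8 genes of CDK inhibitors and the retinoblastoma family, Cdkn1c was 4.23-fold and Cdkn2b 2.05-fold higher (median -0.06). None of 16 p53 targets was past 2-fold (median -0.08). The unfolded protein list held Xbp1 as its member past 2-fold (2.04-fold lower, median -0.10), and the heat shock list held Hspb1 (2.72-fold lower, median 0.04). In the hypoxia and glycolysis list, Pfkp (3.57-fold) and Vegfa (2.96-fold) of 21 genes were lower, with a median of -0.22 just below the random range and inside it under 4 alternatives. Of 16 immediate early genes, Ccn2, Ccn1 (2.79-fold), Jun (2.46-fold) and Zfp36 (2.30-fold) were higher, with a median of 0.23 just above the range and inside it under 4 alternatives.

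Imprinted genes differed in both directions, with more of them higher in the knockout. Of 20 past the filter, 6 were 2-fold higher and 2 lower, and the median of 0.42 was above the random range, -0.24 to 0.21. Those higher were Grb10, Phlda2, Igf2 (4.82-fold), Cdkn1c, Gnas (2.66-fold) and Nnat (2.19-fold), and those lower were Plagl1 and Snrpn (at least 3.82-fold). In the interferon and major histocompatibility list, 5 of 12 were 2-fold higher, namely Psmb8 (at least 5.98-fold), Bst2 (3.57-fold), H2-D1 (2.92-fold), B2m (2.71-fold) and H2-K1 (2.18-fold), and Oas1a was 3.47-fold lower (median 0.67, above all random lists). H2-D1 and H2-K1 are close paralogs whose probe sets can share signal. The 4 passing H2-K1 probe sets had log2 differences of 1.12, 1.19, 0.0084 and -0.05. Of 15 genes of cholesterol synthesis none was past 2-fold, but 11 were above 0, and the median of 0.44 lay above the random range. In the DNA methylation and chromatin list, Dnmt3a and Ring1 (at least 3.46-fold) of 21 genes were higher (median -0.12). In the ribosomal protein list Rps27 (2.38-fold) of 13 was higher (median -0.04), and none of 12 housekeeping genes was past 2-fold (median 0.02).

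The arrays also differed in genes of the sex chromosomes, which moves together with every group above because there was 1 array per genotype. Of 238 X-linked genes past the filter, 197 were lower in the knockout and 51 were 2-fold lower, and the chromosome's median of -0.55 lay below all 10000 random lists. The Y-linked gene Eif2s3y had an intensity of 633 on the knockout array and 2.04 on the wild-type array, and Uty was 2.45-fold higher in the knockout. Of 7 genes in the sex chromosome list, these 2 were 2-fold higher and none was 2-fold lower (median -0.27, inside the range). The other chromosomes had medians between -0.09 and 0.15. Chromosome 8 at 0.15 and chromosome 11 at 0.09 lay above all random lists, and chromosomes 5 (-0.06), 6 (-0.09), 7 (-0.06) and 16 (-0.08) below the 95% range. Chromosome 7 stayed below it under every alternative setting, while 5, 6 and 16 lay inside it under at least 1. Without genes of the X and Y chromosomes, 280 genes were 2-fold higher and 238 were 2-fold lower.

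**Figure D3:**
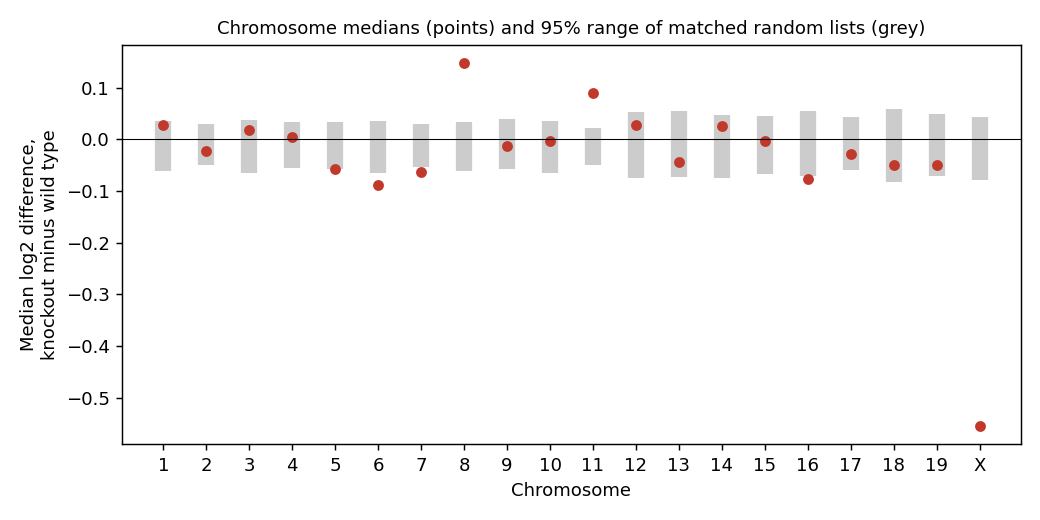
Median log2 difference, knockout minus wild type (vertical), of the genes past the filter on each chromosome (points), with the 95% range of medians of 10000 random lists matched on brightness (grey). Chromosome X stands apart at -0.55, and chromosomes 8 and 11 lie at 0.15 and 0.09.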

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

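The gene comparison left out 2246 probe sets that the annotation assigned to no gene or to several. Of the 972 of these that passed the brightness filter, 38 were at least 2-fold higher on the knockout array than on the wild-type array and 43 at least 2-fold lower, or 3.91% and 4.42%, against 3.92% in each direction for genes. They were singled out because they carry signal in data that the comparison did not use, and none is named here.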

How the results depend on the processing

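Among the results that were rerun, none called in either direction reversed under any alternative. Without the brightness filter 435 genes were higher and 443 lower, with the bright side above the 75th percentile 118 and 131, at 1.5-fold 777 and 847, and at 3-fold 107 and 75. The other alternatives kept both counts within 1.5 times of 289. The filter changes how many genes enter the count, and the fold threshold changes which of the same 7369 genes are counted. Id1 ranged from -1.22 to -1.15 and Nanog from -1.33 to -1.29. The naive list median ranged from -0.93 to -0.80 and the core list from -0.37 to -0.29. The primed list gave 1.03 with log2(value + 32) and 1.93 with the 75th-percentile filter. The epithelial list gave 1.09 without the filter and 1.40 with the 75th-percentile filter. The mesoderm list gave -0.75 with the 75th-percentile filter, below the random range, but on 4 genes. Chromosome X gave -0.49 with log2(value + 32), -0.44 without the filter and -0.62 with the 75th-percentile filter. Chromosome 8 gave 0.18 with the 75th-percentile filter and 0.17 without probe sets ending in _s_at or _x_at, and chromosome 11 gave 0.11 without centring and 0.070 without the filter. Where list or chromosome medians moved, the cause was not tested. Of 13 lists outside the random range, 8 stayed outside it under all 12 alternatives, and 4 of 7 chromosomes did so under the 10 run for chromosomes. For Id1, Nanog, Zeb1 and the genes named for the largest differences or bounds, none of the 332 alternative values obtained fell under 2-fold. A setting in which a gene did not pass the filter or lost its probe set gave no value and is not counted. The other list members named as past 2-fold were not rerun gene by gene. For some of them another passing probe set stayed under 2-fold, as listed above. Of 352 values of the genes that were rerun, Pou5f1 and Sox2 included, 52 moved by more than the probe set spread. Of these, 46 moved to a smaller size, most under another floor or pseudocount. Whether low signal was the reason was not tested. Leaving out a replicate could not be tried with 1 array per genotype. No paired analysis was possible because each genotype has 1 array.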

Other observations

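The tests in this part were chosen after the pattern was seen. The outcome was also known beforehand except for the contractile list with 5 genes held out. The list medians without X-linked members had not been computed, but removing so few members could not have brought them inside the random range. The tests for dilution and fibroblasts were rewritten after their first outcome: the first dilution test compared the SD between pluripotency genes with the probe set spread, a bar that the SD over all filtered genes also exceeds, and the fibroblast test was rewritten more than once, from collagen genes past 2-fold to the rise in intensity over the whole fibroblast list at several bars. The contractile list with Mylpf and Myo1f was also added late.

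A wider set of contractile and actin cytoskeleton genes was higher in the knockout. In a list of such genes written after Tagln, Myl9 and Tpm1 had been seen, 11 of 31 genes past the filter were 2-fold higher and none was 2-fold lower. The list leaves out the myosin genes Mylpf (4.77-fold lower) and Myo1f (at least 9.23-fold lower). Those higher included the calponin genes Cnn1 (at least 5.03-fold) and Cnn2 (2.77-fold), the tropomyosin genes Tpm4 (3.14-fold) and Tpm2 (2.08-fold), the focal adhesion gene Zyx (3.02-fold), Csrp1 (2.47-fold) and the caldesmon gene Cald1 (2.31-fold). Tagln, Myl9, Tpm1, Cnn1 and Acta2 were then held out. Among the 26 members left, 7 were 2-fold higher, 19 were above 0 and the median was 0.34. It lay above all 10000 random lists (95% range -0.19 to 0.14), so brightness alone does not give such a median. With 1 array per genotype, the range says nothing about chance differences between cultures. With Mylpf and Myo1f added to the 26, the median was 0.31, above all random lists. Adding 2 genes to 26 could not have brought the median inside the random range, however low they were. This median therefore adds no separate support. Fibroblasts left in the knockout culture could bring such transcripts, and this stays open. They would bring their other abundant transcripts too. The collagen genes read 133 against 83.0 (Col1a1), 199 against 194 (Col1a2) and 38.3 against 69.0 (Col3a1). Col1a1 and Col3a1 did not reach the filter on either array, so these values cannot decide the question. Tagln rose by 1578 in intensity, and of the 20 other fibroblast list genes, with the contractile gene Acta2 left out, 6 rose by at least 2% of that, 2 by at least 5% and 1 by at least 10%. Intensities of different probe sets are not on a common scale and no fibroblast array gives the level to expect, so these counts exclude nothing. Fstl1 (2.71-fold) and Thbs1 (2.67-fold) were higher, and the fibroblast list median of 0.43 lay above the random range in the chosen setting. A difference in cell spreading or in the state of the culture stays open, as does an effect of Id1, and neither was tested.

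Genes of the X chromosome were lower on the knockout array as a group. Scaling does not account for this, since the median of chromosome X was no higher than -0.53 under the 4 scalings, and neither does loss of a single region, since all 6 of 6 consecutive segments of the chromosome lay below the random range. A candidate explanation is that the wild-type line carried 2 active X chromosomes and the knockout line 1 X and a Y: 2 of 3 Y-linked genes past the filter, Eif2s3y and Uty, were 2-fold higher in the knockout. Xist, the RNA that silences an X chromosome, read 271 in the knockout and 513 in the wild type (log2 difference -0.95) by the probe set past the filter, with its other two at the floor on both arrays, so whether both X chromosomes were active in the wild type is not settled by it. The third, Tspy-ps, had intensities of 122 in the knockout and 236 in the wild type, and Kdm5d did not reach the filter on either array. This remains a hypothesis until the lines are karyotyped.

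Naive pluripotency genes were lower (median -0.86) and primed epiblast genes higher (median 1.23) on the knockout array. X-linked members are too few to carry this, with 1 of 17 naive genes and 2 of 15 primed genes. Without Nr0b1 the naive median was -0.83 and without Sox3 and Pim2 the primed median was 1.23, both outside the random range. Removing so few members could not have brought either median inside it, so these medians add no separate support. Dilution by cells without pluripotency transcripts would lower all pluripotency genes alike. However, 6 of 14 core genes lay above the naive median by more than 2 robust SD of bright genes (0.31 each). Of these, 5 were above 0 by their brightest probe set (for Lin28a, by 1 of 2 passing probe sets). These values argue against such cells as the whole cause of the lower naive genes, with a bar set after the values were known. They do not speak to dilution by a smaller share, or by cells that keep core pluripotency transcripts. It stays open whether the pattern goes with Id1, with the number of X chromosomes acting on other genes, or with the line: there were 0 arrays that separate genotype from sex chromosomes, so these cannot be told apart. The X-linked ERK phosphatase gene Dusp9 (3.50-fold lower), the ERK feedback gene Dusp6 (2.55-fold higher) and Dnmt3a (3.54-fold higher) would be the genes to measure in knockout and wild-type lines of the same sex.

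Of the 20 nearest genes on the array around Id1, 10 on each side in the gene order of GRCm38.p6, 16 passed the filter, with a median of -0.14 inside the random range of -0.24 to 0.24. The nearest on one side, the imprinted pair Mcts2 and H13, had log2 differences of -0.81 and 1.19, and Cox4i2 on the other side had -0.66. Consecutive segments of chromosome 8 had medians from 0.04 to 0.22, with 4 of 6 above the random range, and those of chromosome 11 from 0.05 to 0.18, with 3 of 6 above it.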
